A study of Mus musculus with 16 samples.

How the data were processed

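RNA of mouse embryonic stem cells of mixed C57BL/6, C3H and CD1 background was hybridized to 16 Illumina mouse bead arrays with 25697 probes. Per the labels, the samples are 0, 3, 6, 9, 12, 24 and 48 h of E1A induction and a cherry control at 48 h, with 2 arrays each.

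The deposited raw table holds 1 signal intensity per probe and array, in linear intensity units before any normalization, per the file headers. Beside each intensity the deposited table holds a detection p-value, which compares the probe with background. The deposited series matrix holds values on a log2 scale with a median of 4.1321 on every array, and its array quantiles were identical within 0.00108. Its rank order within each array was that of the raw intensities. The submitters' processing notes name BeadStudio 3.2, RMA and lumi, whose order and role are not stated. The raw intensities were used for the main results, and the deposited log2 values for an alternative. All value columns were matched to samples.

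Intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values, an offset of 16 and quantile normalization, on the log2 scale. Probes were kept if their detection p was below 0.05 on both arrays of at least 1 group, which left 13327. The array annotation gave 1 gene symbol to 23978 probes, and 1719 probes unnamed here were kept under their probe identifiers. Each gene was represented by the probe with the highest mean level. This left 9987 features, 9193 named genes and 794 unnamed probes. The detection rate of 47.2% to 49.2% limits what can be seen of genes with low signal.

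All 8 groups were fitted in 1 linear model with 1 mean per group (lmFit and eBayes of limma, 8 residual and 6.2 prior degrees of freedom), and contrasts were tested with the moderated t-test. P-values were adjusted over all 9987 features by the Benjamini-Hochberg method, and features with an adjusted p below 0.05 were called. SE is the moderated standard error of the log2 fold change, and SD is given between the 2 arrays of a group. The comparisons were 48 h of E1A against the control at 48 h, each time and the control against 0 h, an F test over the E1A time course, and the difference of the effect at 24 h (against 0 h) and the effect at 48 h (against the control). These choices were made before the data were examined.

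Lists of 28 gene groups were also written before the data were examined, from general knowledge. They cover E2F targets and DNA replication, the G2/M phase, core and naive pluripotency, primed epiblast, primitive streak and mesoderm, primitive and definitive endoderm, trophectoderm, neural genes, mouse embryonic fibroblast markers, mesenchymal transition, epithelial genes, TGF-beta, SMAD and YAP targets, WNT targets, retinoic acid response, interferon response, NF-kB and inflammatory genes, p53 targets and apoptosis, the 2-cell-like state, germline and meiosis, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein and integrated stress response, heat shock, MYC targets and ribosome biogenesis, core histones, immediate early genes, oxidative phosphorylation and host partners of E1A. Lists with at least 5 tested members were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01, adjusted over the 28 lists. List tests for 48 h of E1A against the control, 24 h against 0 h and the control against 0 h were planned, and those at 3, 6, 9, 12 and 48 h against 0 h and for the difference were added after the data were examined.

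The named genes follow a rule written before the data were examined. For 48 h of E1A against the control they are the 8 largest positive and 8 largest negative differences among called genes. In each, the 2 values of a group lie above both of the other. Symbols made of Gm or LOC and a digit, symbols ending in Rik and unnamed probes were left out. For every other contrast they are the 4 largest in each direction by the same rule, and for each list described up to 3 called members with the largest change. Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Ccne1, Ccne2, Cdkn1a, Myc, Cdh1 and Rb1 are named whatever their values. Within this rule, list members whose call depends on 1 array were mostly left unnamed. The collagens Col1a1, Col1a2 and Col3a1 were named after their values were seen.

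The 0 h arrays serve as control in 7 comparisons. The resulting correlation was measured on 100 simulated data sets with unchanged groups. The pipeline was tested on simulated data with 200 changed genes, where 65% of changes of 0.5 and 100% of changes of 1 on the log2 scale were recovered in the comparison at 48 h. There were 8 false calls among 173 calls over both sizes, and 0 calls in a contrast without changes. A list of 20 members shifted by 0.3 was found and 0 others were. This does not show how often camera makes false calls in the measured data, where genes of a list may vary together.

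Alternatives were no background correction, an offset of 50, scaling to the 75th percentile, the deposited log2 values, no detection filter, detection p below 0.01 on all arrays, all probes unmerged, eBayes with trend and robust fitting, only the compared groups in the fit, the replicate number as a block, a minimum log2 fold change of 1, camera with an estimated correlation, the rotation test fry, and leaving out each array in turn. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.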

Results

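Messenger RNA of mouse embryonic stem cells was measured on 16 Illumina bead arrays, in 8 groups of 2 arrays each. The groups follow induction of E1A, the early adenoviral protein that binds host regulators such as the retinoblastoma family, at 0, 3, 6, 9, 12, 24 and 48 h. The remaining group is a control at 48 h that the labels call cherry. The labels do not say whether the 0 h cells and the control cells carry the same construct, nor whether the control cells make any E1A. The series concerns the steps of reprogramming to pluripotency that run without Sox2. Between 47.2% and 49.2% of the 25697 probes were above background on each array, and the median raw intensity per array lay between 122 and 136. Replicate arrays correlated across genes with Pearson's r of 0.996 to 0.997, where genes are not independent replicates, and the SD of the difference between replicates was 0.164 to 0.201 on the log2 scale. The origin of the replicates is not stated, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

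The main comparison asked what differed after 48 h between cells with E1A and the cherry control. For this comparison, rose, fell and changed describe the level with E1A relative to the control at 48 h, not a course over time. The actin genes Acta1 and Acta2 and the matrix enzyme gene Lox were higher with E1A, and the lists of pluripotency genes and of genes of the embryo at the 2-cell stage were lower. Acta1, which encodes skeletal muscle actin, had a mean log2 level of 9.95 ± 0.15 with E1A and 6.74 ± 0.14 in the control (SD, n = 2 arrays per group), a 9.24-fold difference. Acta2, smooth muscle actin, was 4.43-fold higher and Lox, an enzyme that crosslinks collagen, 3.47-fold higher. Zscan4c, a gene of the embryo at the 2-cell stage, had a level of 9.37 ± 0.03 with E1A and 11.15 ± 0.08 in the control (SD, n = 2), and was 3.43-fold lower with E1A. In limma with Benjamini-Hochberg adjustment, 2141 of 9987 genes and unnamed probes differed, 1088 higher and 1053 lower with E1A, and 171 of them by at least 2-fold, 56 higher and 115 lower. With scaling to the 75th percentile, 927 were higher and 1088 lower. The count was 1287 without 48h replicate 1, 1328 without 48h replicate 2 and 1413 without 48h control replicate 2.

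Among the genes highest against the control, Acta1 differed by 3.21 on the log2 scale (SE 0.133, adjusted p = 1.63e-09). Rec8, a meiotic cohesin, changed by 2.40 (SE 0.0913, adjusted p = 6.12e-10) and Acta2 by 2.15 (SE 0.0814, adjusted p = 6.12e-10). Rgma, a co-receptor for bone morphogenetic proteins, changed by 2.11 (SE 0.203, adjusted p = 4.64e-06) and Fgfbp1, which binds fibroblast growth factors, by 2.01 (SE 0.123, adjusted p = 6.71e-08). Lox was higher by 1.80 (SE 0.112) and Cldn4, a tight junction claudin, by 1.75 (SE 0.0979). Against 0 h, Acta2 was at 0.971 with E1A and -1.18 in the control, so a fall in the control can enter such differences. Spen, a transcriptional repressor, was not above background in the control, and was at least 3.62-fold higher with E1A. Where a group has no array above background, its level is set no lower than the faintest detected value of each array, and the fold is given as a lower bound.

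Among the genes lowest against the control, AF067063 differed by -1.94 (SE 0.179, adjusted p = 3.01e-06) and Cbln1, a synapse organizer, by -1.87 (SE 0.145, adjusted p = 6.02e-07). Such a difference can also come from a rise in the control since 0 h. Vstm2l changed by -1.84 (SE 0.156) and Jam2, a junctional adhesion molecule, by -1.82 (SE 0.0938, adjusted p = 1.42e-08), while its other probes gave -1.52, -0.87 and -0.79. Pramel20 changed by -1.80 (SE 0.132) and Zscan4c by -1.78 (SE 0.0876, adjusted p = 9.7e-09). Pramel7 and Tmem92 were not above background with E1A. They were at least 3.12-fold and at least 3.28-fold lower than in the control.

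**Figure D1:**
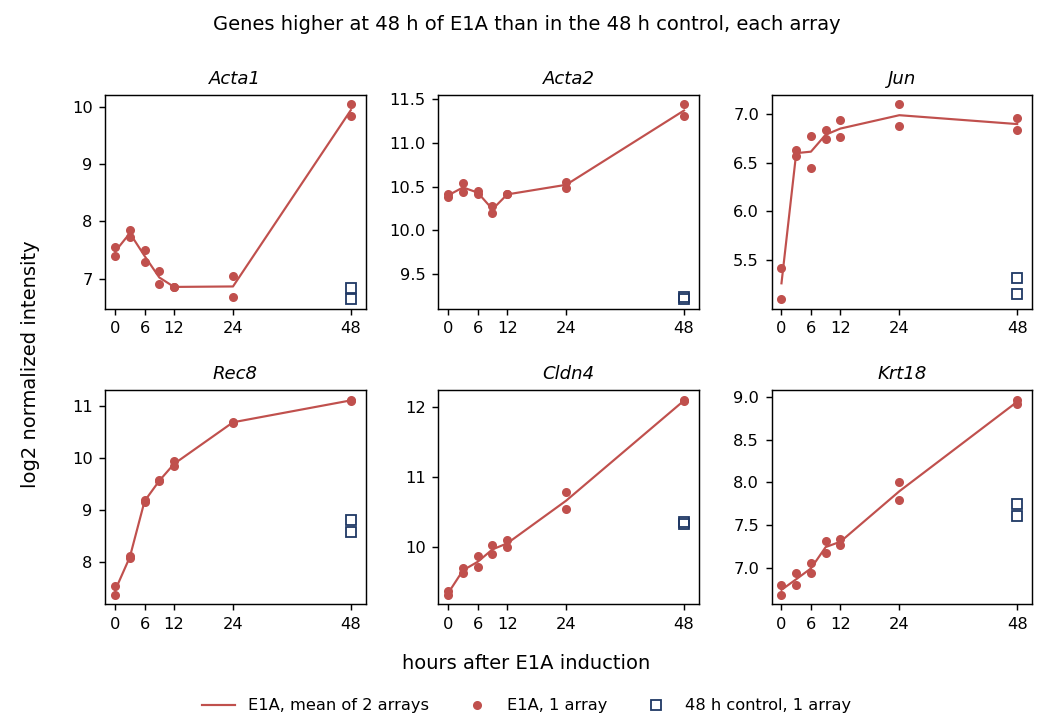
Log2 normalized intensity of 6 genes against hours after E1A induction, with each array as a point, the mean of 2 arrays as a line and the control arrays at 48 h as open squares. Acta1 reached 9.95 at 48 h of E1A and 6.74 in the control, and Jun was higher at 3 h than at 0 h.

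The core and naive pluripotency list had 20 of 29 tested members lower with E1A and 3 higher, while 6 did not pass the test. Adjusted over the list alone, 20 were lower and 4 higher. The median log2 fold change was -0.57, and the list differed from other genes in limma's camera (adjusted p = 1.7e-09). Tdgf1, the Nodal co-receptor Cripto, fell by 1.71 on the log2 scale (SE 0.127, adjusted p = 3.9e-07) and Fgf4, a growth factor that Pou5f1 and Sox2 regulate, by 1.54 (SE 0.113, adjusted p = 3.49e-07). Tbx3, a naive state regulator, fell by 1.29 (SE 0.097), and its other probes gave -1.47 and -0.56. The core factor Pou5f1 fell by 0.91 (SE 0.0828, adjusted p = 2.69e-06), from a level of 12.05 ± 0.05 in the control to 11.14 ± 0.01 (SD, n = 2). Klf4 was lower than in the control by 1.12 (SE 0.109, adjusted p = 4.82e-06), Esrrb by 0.72 (SE 0.0909) and Zfp42 by 0.56 (SE 0.0937, adjusted p = 0.000634), all markers of the naive state. Against 0 h, Klf4 was at -0.139 with E1A and 0.985 in the control, and Esrrb and Nanog also rose in the control. Pou5f1 was at -1.69 with E1A and -0.788 in the control against 0 h. Sox2 fell by 0.64 (SE 0.145, adjusted p = 0.00544), with an adjusted p of 0.0629 without 48h replicate 1 and 0.0798 without 48h control replicate 2. Nanog fell by 0.38 (SE 0.101, adjusted p = 0.0148), with an adjusted p of 0.0574 without 48h replicate 1, 0.0876 without 48h replicate 2 and 0.0922 without 48h control replicate 2.

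**Figure D2:**
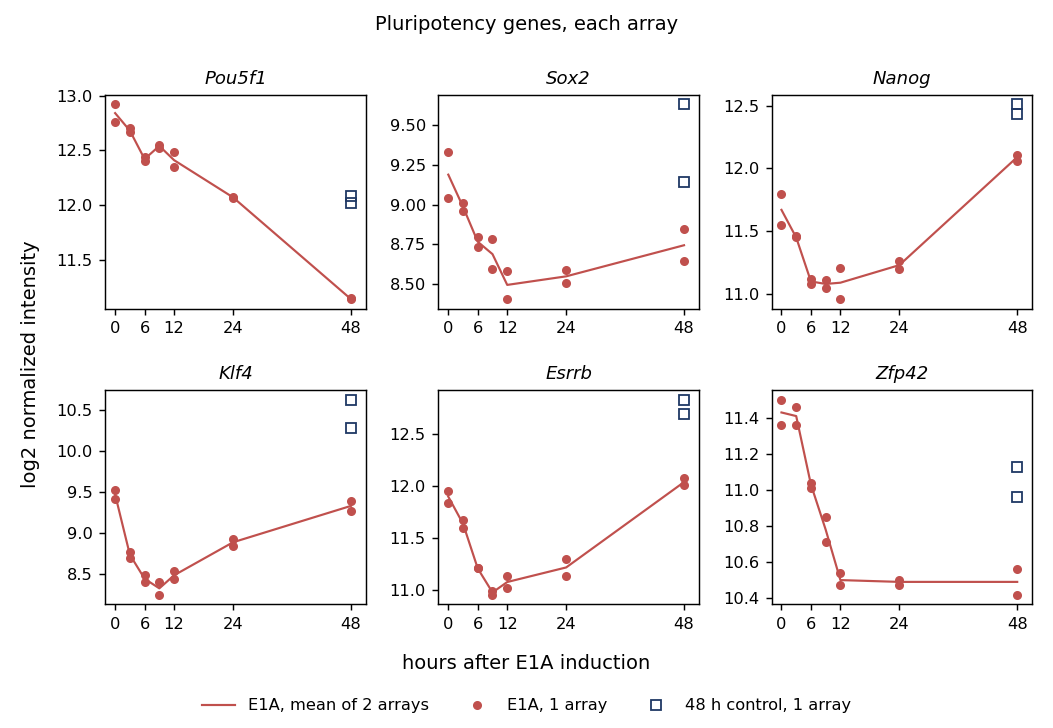
Log2 normalized intensity of 6 pluripotency genes against hours after E1A induction, with each array as a point, the mean of 2 arrays as a line and the control arrays at 48 h as open squares. Pou5f1 was at 12.84 at 0 h, 11.14 at 48 h of E1A and 12.05 in the control.

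The 2-cell-like list, genes of the embryo at the 2-cell stage and of a rare state in stem cell cultures, had all 11 tested members lower with E1A than in the control. Adjusted over the list alone all 11 were lower, the median was -1.54 with or without members at their bound, and camera gave an adjusted p of 2.1e-15. Zscan4c, Pramel7 and Tmem92, given above, changed most. Several members belong to families of near-identical copies, such as Zscan4 and Tcstv, whose probes may read more than 1 copy. All 11 members rose in the control between 0 h and 48 h, with a median of 0.97, or 0.79 with members at their bound.

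**Figure D3:**
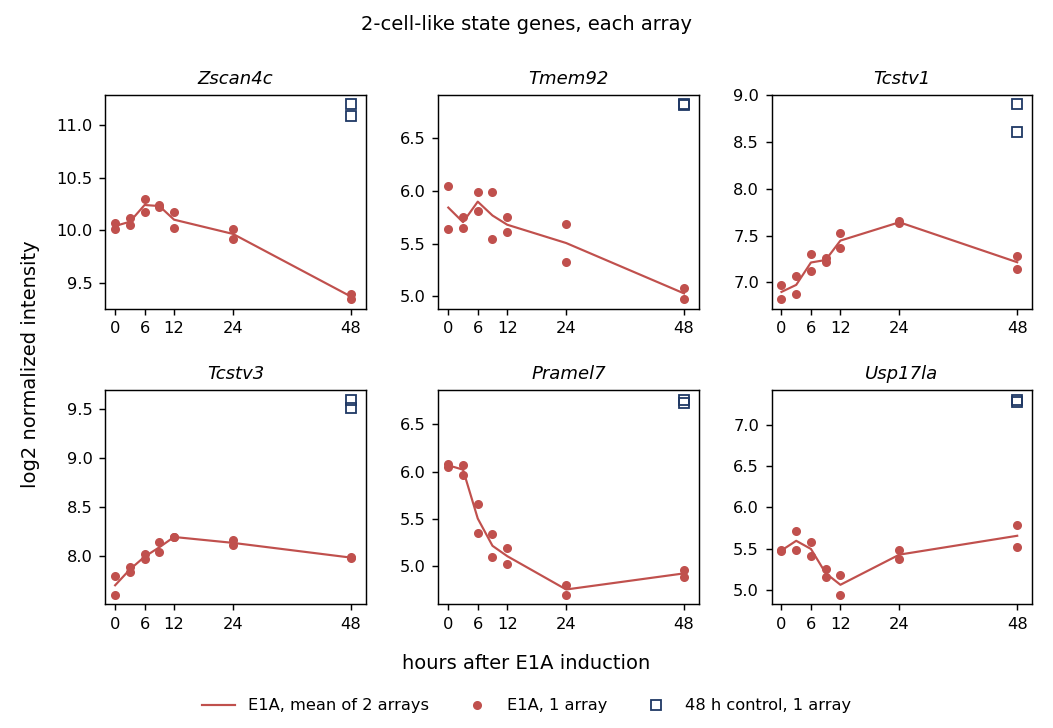
Log2 normalized intensity of 6 members of the 2-cell-like list against hours after E1A induction, with each array as a point, the mean of 2 arrays as a line and the control arrays at 48 h as open squares. Zscan4c was at 9.37 at 48 h of E1A and 11.15 in the control.

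The lists of TGF-beta, fibroblast and mesenchymal genes each had more members higher than lower with E1A. The TGF-beta, SMAD and YAP target list had 8 of 16 members higher and 1 lower, and 10 higher and 1 lower adjusted over the list alone (median 0.40, camera adjusted p = 0.000472). Ccn1, a matrix protein induced by YAP, rose by 1.23 (SE 0.155, adjusted p = 5.5e-05). Ankrd1, another YAP target, rose by 0.94 (SE 0.131, other probe 0.63) and Id1, a BMP target, by 0.88 (SE 0.118). Id1 was below its 0 h level in both arms, at -0.644 with E1A and -1.52 in the control. The mouse embryonic fibroblast list had 7 of 13 members higher and 1 lower, and 8 higher and 2 lower adjusted over the list alone (median 0.45, or 0.36 with members at their bound, camera adjusted p = 0.00091). Its members Acta2 and Lox are given above, and Bgn, the proteoglycan biglycan, rose by 1.12 (SE 0.119, adjusted p = 1.09e-05). The fibroblast matrix genes Col1a1, Col1a2 and Col3a1 were above background on no array at 48 h of E1A. The mesenchymal transition list had 9 of 18 members higher and 2 lower, with the same counts adjusted over the list alone (median 0.30, camera adjusted p = 0.00626, adjusted p = 0.235 with an estimated correlation). Tpm1, a tropomyosin, was higher by 1.06 (SE 0.0876) and Zyx, an adhesion protein, by 0.84 (SE 0.0863). Tgfbi, a matrix protein, was lower than in the control by 1.11 (SE 0.11). Against 0 h Tgfbi rose in both arms, by 2.12 with E1A and by 3.24 in the control.

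Immediate early genes, which respond first to growth signals, had 8 of 17 members higher and 0 lower, also adjusted over the list alone (median 0.30, camera adjusted p = 5.99e-05). Jun and Fos, which form the AP-1 factor, were each higher than in the control by 1.66 (SE 0.132 and 0.102, adjusted p = 7.02e-07 and 6.58e-08). Egr1, a zinc finger factor, was higher by 1.35 (SE 0.0863). It had fallen by more than this in the control since 0 h, so it was below its 0 h level in both arms. The trophectoderm list had 8 of 20 members higher and 2 lower, and 8 higher and 3 lower adjusted over the list alone (median 0.19, camera adjusted p = 0.045, adjusted p = 0.114 with an estimated correlation). Its keratins Krt18 and Krt8, filament proteins of simple epithelia, rose by 1.26 (SE 0.0994) and 1.19 (SE 0.0903). Without 48h replicate 1 the adjusted p of this list was 0.0635, with the stricter detection filter 0.099, with all probes 0.107 and with only the compared groups 0.0586. With an estimated correlation, 5 of the 7 list calls of this comparison held, and the mesenchymal and trophectoderm lists lost theirs.

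Cell cycle genes had no common direction at 48 h of E1A against the control. In the list of E2F targets and DNA replication, 6 of 32 members were higher and 2 lower (7 and 2 adjusted over the list alone, median 0.062, camera adjusted p = 0.464). Ccne1, cyclin E1, rose by 0.44 (SE 0.0893, adjusted p = 0.00281) and Mybl2, a cell cycle transcription factor, fell by 0.89 (SE 0.0971, adjusted p = 1.53e-05). Ccne2, cyclin E2, had a log2 fold change of 0.092 (adjusted p = 0.765), the cell cycle inhibitor Cdkn1a of -0.23 (adjusted p = 0.101), Rb1, the retinoblastoma protein that E1A binds, of -0.18 (adjusted p = 0.233) and Cdh1, E-cadherin, of 0.11 (adjusted p = 0.434). Myc was not above background in either group. The median of the G2/M list was 0.056 (adjusted p = 0.485), of MYC targets and ribosome biogenesis 0.027 (mean -0.012, adjusted p = 0.784), of p53 targets and apoptosis -0.022 (adjusted p = 0.876), of core histones -0.010 (mean 0.13, adjusted p = 0.386) and of host partners of E1A 0.10 (adjusted p = 0.21).

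The other lists of this comparison did not pass camera with the chosen settings, though some did under others. For lineages, the median was -0.084 for primed epiblast (-0.066 with members at their bound, adjusted p = 0.528), -0.17 for primitive streak and mesoderm (adjusted p = 0.1), 0.15 for endoderm (adjusted p = 0.494), -0.12 for neural genes (-0.030 with members at their bound, adjusted p = 0.294), 0.19 for epithelial genes (0.14 with members at their bound, adjusted p = 0.143) and -0.19 for germline and meiosis genes (adjusted p = 0.114). For signalling, it was -0.20 for WNT targets (mean 0.058, adjusted p = 0.784), 0.093 for the retinoic acid response (adjusted p = 0.876), 0.034 for the interferon response (adjusted p = 0.876) and -0.32 for NF-kB and inflammatory genes (adjusted p = 0.0502). For metabolism and stress, it was -0.019 for glycolysis and hypoxia (adjusted p = 0.494), -0.12 for cholesterol synthesis (adjusted p = 0.139), -0.11 for oxidative phosphorylation (adjusted p = 0.0583), -0.073 for the unfolded protein and integrated stress response (adjusted p = 0.21) and -0.0041 for heat shock genes (mean 0.000448, adjusted p = 0.918). Without 48h replicate 1 the streak list reached 0.0441 and the NF-kB list 0.0214. Without 48h control replicate 1 the NF-kB list reached 0.0481, the oxidative phosphorylation list 0.0423 and the cholesterol list 0.0318. With scaling to the 75th percentile the adjusted p was 0.0442 for the streak list, 0.0398 for the NF-kB list and 0.0172 for oxidative phosphorylation, and with the deposited values it was 0.043 for each, all lower with E1A. The NF-kB and oxidative phosphorylation lists also passed with no background correction (0.0174 and 0.0275), an offset of 50 (0.0277 and 0.0473), all probes (0.0315 and 0.0343) and trend and robust fitting (0.026 and 0.0337). With all probes the germline list reached 0.0112, and with no detection filter oxidative phosphorylation reached 0.0291.

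**Figure D4:**
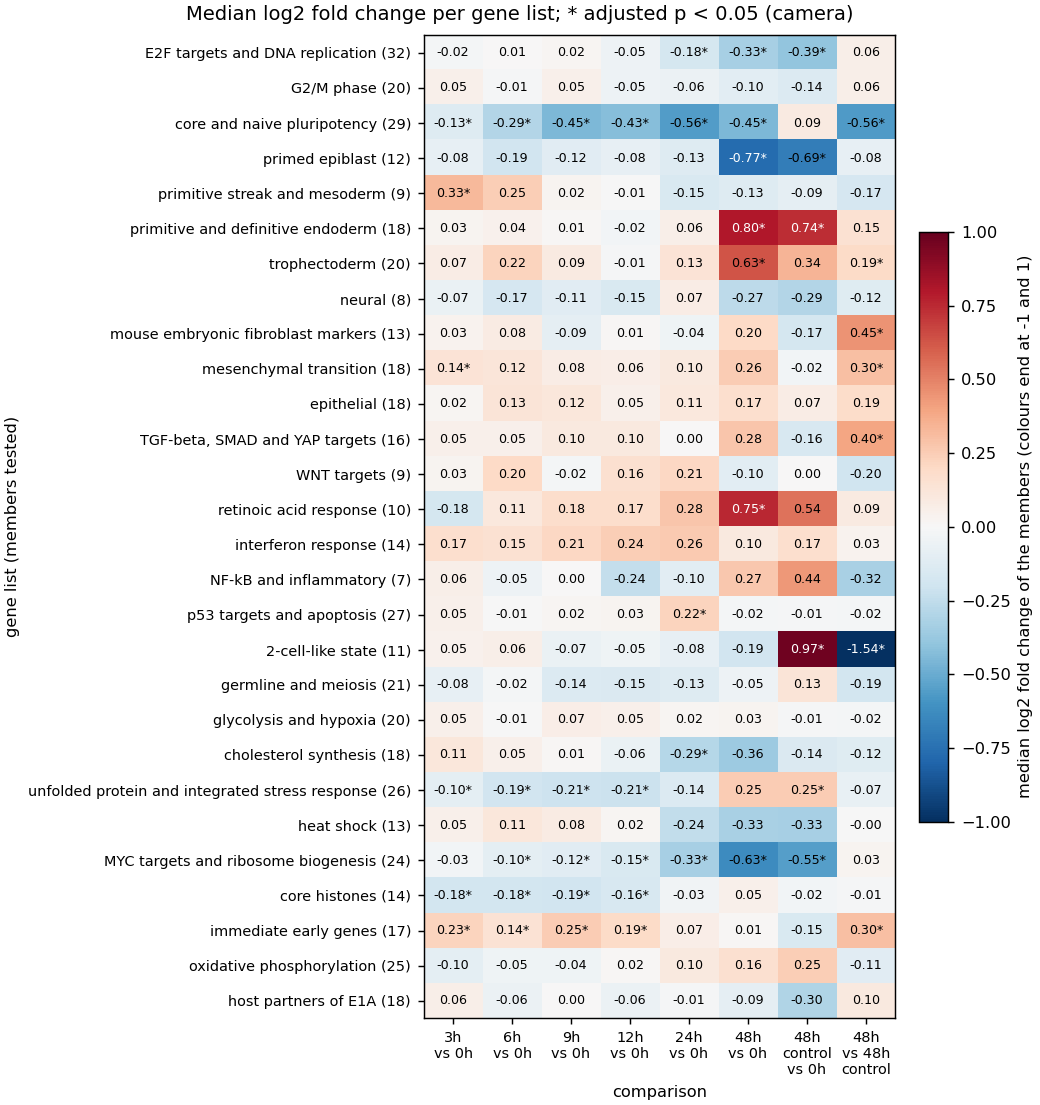
Median log2 fold change of the tested members of 28 gene lists in 8 comparisons, with the number of members in brackets and an asterisk where camera's adjusted p was below 0.05. The pluripotency list was lower at every time of E1A against 0 h, with medians from -0.13 at 3 h to -0.56 at 24 h.

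The early times were compared with 0 h. From 3 h to 24 h no control of the same time entered the comparisons, so E1A and time are not separated there. Within 3 h Id4, an inhibitor of helix-loop-helix factors, was 4.52-fold higher than at 0 h, rising from 5.22 ± 0.06 to 7.40 ± 0.03 on the log2 scale (SD, n = 2). Jun, above background on 1 of 2 arrays at 0 h, was 2.52-fold, Spen 2.94-fold and Msc, the transcription factor musculin, 2.45-fold higher. Chac1, a glutathione-degrading enzyme of the stress response, was 3.09-fold lower, and Inhbb, a subunit of activin, 2.06-fold lower. Id4 rose by 2.18 (SE 0.101, adjusted p = 3.08e-08), and Chac1 fell by 1.63 (SE 0.108, adjusted p = 1.84e-06), Cryl1 by 1.12 (SE 0.122) and Slc1a4, an amino acid transporter, by 1.08 (SE 0.0927). In limma, 151 genes were higher and 96 lower at 3 h, 247 in all. The count was 80 without 0h replicate 1, 157 without 0h replicate 2, 100 without 3h replicate 1 and 104 without 3h replicate 2.

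At 3 h, 7 of 17 immediate early genes were higher and 0 lower (8 and 1 adjusted over the list alone, median 0.23, or 0.19 with members at their bound, camera adjusted p = 1.18e-07). Fos rose by 1.03 (SE 0.102) and Egr1 by 0.85 (SE 0.0863). In the unfolded protein and integrated stress response list 6 of 26 members were lower and 0 higher (8 and 0 adjusted over the list alone, median -0.10, adjusted p = 8.9e-07), among them Atf4, the central factor of the integrated stress response, which fell by 0.69 (SE 0.0904), and Herpud1 by 0.66 (SE 0.0933). In the pluripotency list 3 members were lower and 1 higher (5 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.00292). Klf2 and Klf4, paired naive state factors, fell by 0.95 (SE 0.12) and 0.73 (SE 0.109). The log2 fold changes of Pou5f1, Sox2 and Nanog at 3 h were -0.16, -0.20 and -0.22 (adjusted p = 0.352, 0.5 and 0.275). The primitive streak list had 3 of 9 members higher (6 adjusted over the list alone, median 0.33, or 0.30 with members at their bound, adjusted p = 0.000524, adjusted p = 0.125 with an estimated correlation), and the mesenchymal list 3 of 18 (4 adjusted over the list alone, median 0.14, adjusted p = 0.000977, adjusted p = 0.144 with an estimated correlation). Zyx rose by 0.80 (SE 0.0863). Core histones had 1 of 14 members lower (3 adjusted over the list alone, median -0.18, or -0.17 with members at their bound, adjusted p = 0.00114).

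By 6 h Id4 was 10.9-fold above its 0 h level, the largest rise at that time, at 3.44 on the log2 scale (SE 0.101, adjusted p = 5.1e-11). Spen was 3.65-fold and Pou3f1, a factor of the primed epiblast, 3.47-fold higher. Hspa1a, an inducible heat shock protein that was above background on 1 of the 2 arrays at 0 h, was 3.59-fold higher. Chac1 fell by 1.67 (SE 0.108), Taf15, an RNA-binding protein, by 1.52 (SE 0.115), Tatdn2 by 1.47 (SE 0.0875) and Inhbb by 1.38 (SE 0.166). In limma, 785 genes were higher and 462 lower, 1247 in all. The count was 522 without 0h replicate 1, 761 without 0h replicate 2, 458 without 6h replicate 1 and 764 without 6h replicate 2.

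At 6 h the pluripotency list had 10 of 29 members lower and 0 higher (17 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 2.25e-09). Klf2 fell by 1.16 (SE 0.12), Klf4 by 1.03 (SE 0.109), Esrrb by 0.68 (SE 0.0909) and Nanog by 0.58 (SE 0.101, adjusted p = 0.00225), while Sox2 had a log2 fold change of -0.42 (adjusted p = 0.0717). The stress response list had 9 of 26 members lower (10 adjusted over the list alone, median -0.19, adjusted p = 7.16e-07), with Nupr1, a stress-induced chromatin protein, at -1.05 (SE 0.106) and Atf4 at -0.82 (SE 0.0904). Core histones had 3 of 14 members lower (5 adjusted over the list alone, median -0.18, adjusted p = 0.00282, adjusted p = 0.0539 with an estimated correlation), and MYC targets 3 of 24 (4 adjusted over the list alone, median -0.096, adjusted p = 0.0211, adjusted p = 0.105 with an estimated correlation, 0.0599 without 0h replicate 2 and 0.0542 with the stricter detection filter). Immediate early genes had 8 of 17 members higher and 2 lower, also adjusted over the list alone (median 0.14, adjusted p = 0.0498, adjusted p = 0.26 with an estimated correlation). Without 0h replicate 2 their adjusted p was 0.133, without 6h replicate 2 it was 0.0558, with the deposited values 0.065, with the stricter detection filter 0.0527 and with only the compared groups 0.157.

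At 9 h Id4 was 10.2-fold, Rec8 4.29-fold, Hspa1a 3.87-fold and Pou3f1 3.56-fold higher than at 0 h. Inhbb was 3.29-fold, Bcl3, a nuclear partner of NF-kB, 2.61-fold, Chac1 2.57-fold and Taf15 2.54-fold lower. Rec8 rose by 2.10 (SE 0.0913, adjusted p = 5.96e-09) and Inhbb fell by 1.72 (SE 0.166, adjusted p = 1.54e-05). In limma, 680 genes were higher and 483 lower, 1163 in all. The count was 648 without 0h replicate 1, 724 without 0h replicate 2, 546 without 9h replicate 1 and 707 without 9h replicate 2. In the pluripotency list 18 of 29 members were lower and 2 higher (20 and 3 adjusted over the list alone, median -0.45, camera adjusted p = 1.83e-10), with Klf2 at -1.27 (SE 0.12), Klf4 at -1.14 (SE 0.109), Esrrb at -0.92 (SE 0.0909) and Zfp42 at -0.65 (SE 0.0937). Lefty1, an inhibitor of Nodal, rose by 1.08 (SE 0.106). The stress response list had 9 of 26 members lower, also adjusted over the list alone (median -0.21, adjusted p = 6.48e-07). Immediate early genes had 8 of 17 higher and 2 lower (9 and 3 adjusted over the list alone, median 0.25, adjusted p = 0.00467, adjusted p = 0.122 with an estimated correlation). MYC targets had 4 of 24 lower, also adjusted over the list alone (median -0.12, adjusted p = 0.00548, adjusted p = 0.063 with an estimated correlation), and core histones 3 of 14 (also adjusted over the list alone, median -0.19, adjusted p = 0.0027, adjusted p = 0.0531 with an estimated correlation).

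At 12 h Id4 was 8.65-fold, Rec8 5.37-fold, Efnb1, a membrane ligand of Eph receptors, 4.45-fold and Spen 3.63-fold higher than at 0 h. Inhbb was 3.77-fold, Bcl3 2.75-fold and Nkain1 2.62-fold lower, and BC051019, not above background at 12 h, at least 2.21-fold lower. Efnb1 rose by 2.15 (SE 0.137, adjusted p = 3.76e-07) and Lefty1 by 1.66 (SE 0.106). In limma, 952 genes were higher and 669 lower, 1621 in all, and 1150 were higher and 575 lower with scaling to the 75th percentile. The count was 964 without 0h replicate 1, 933 without 0h replicate 2 and 967 without 12h replicate 1. In the pluripotency list 15 of 29 members were lower and 2 higher (21 and 2 adjusted over the list alone, median -0.43, camera adjusted p = 7.34e-10). Klf2 fell by 1.36 (SE 0.12), Klf4 by 0.98 (SE 0.109), Zfp42 by 0.93 (SE 0.0937), Esrrb by 0.81 (SE 0.0909), Nanog by 0.59 (SE 0.101) and Pou5f1 by 0.43 (SE 0.0828). The stress response list had 11 of 26 members lower (12 adjusted over the list alone, median -0.21, adjusted p = 1.76e-06). Immediate early genes had 8 of 17 higher and 2 lower (8 and 3 adjusted over the list alone, median 0.19, adjusted p = 0.0188, adjusted p = 0.205 with an estimated correlation). MYC targets had 5 of 24 lower (6 adjusted over the list alone, median -0.15, adjusted p = 0.00249). Core histones had 2 of 14 lower, also adjusted over the list alone (median -0.16, or -0.10 with members at their bound, adjusted p = 0.0476, adjusted p = 0.185 with an estimated correlation), with an adjusted p of 0.0995 without 0h replicate 1 and 0.154 without 12h replicate 1. It was 0.0973 with no background correction, 0.0924 with an offset of 50, 0.0728 with scaling to the 75th percentile, 0.175 with the stricter detection filter, 0.0667 with all probes and 0.0893 with trend and robust fitting.

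At 24 h Rec8 was 9.34-fold, Efnb1 7.05-fold, Id4 6.32-fold and Lefty1 5.6-fold higher than at 0 h. Inhbb was 6.73-fold, Enox1, a cell surface oxidase, 4.49-fold, Bmp4, a bone morphogenetic protein, 3.73-fold and the growth factor Fgf17 3.27-fold lower. Rec8 changed by 3.22 (SE 0.0913, adjusted p = 3.04e-11) and Inhbb by -2.75 (SE 0.166, adjusted p = 5.97e-08). The epithelial genes Cldn4, Krt18 and Krt8 rose by 1.32 (SE 0.0979), 1.15 (SE 0.0994) and 1.13 (SE 0.0903), while the epithelial list had 5 of 18 members higher and 3 lower, also adjusted over the list alone, and did not pass camera (median 0.11, or 0.066 with members at their bound, adjusted p = 0.431). In limma, 1792 genes were higher and 1450 lower, 3242 in all, 221 of them by at least 2-fold.

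At 24 h the pluripotency list had 21 of 29 members lower and 2 higher (25 and 2 adjusted over the list alone, median -0.56, camera adjusted p = 2.22e-09). Pou5f1 fell by 0.77 (SE 0.0828, adjusted p = 9.29e-06), Zfp42 by 0.95 (SE 0.0937), Esrrb by 0.67 (SE 0.0909) and Klf4 by 0.58 (SE 0.109). Sox2 fell by 0.64 (SE 0.145, adjusted p = 0.00369), with an adjusted p of 0.0511 without 0h replicate 2 and a value of -0.19 from its other probe, and Nanog by 0.44 (SE 0.101, adjusted p = 0.0041), with an adjusted p of 0.0601 without 0h replicate 1. Among p53 targets and apoptosis genes, 13 of 27 were higher and 3 lower, also adjusted over the list alone (median 0.22, adjusted p = 0.0041). Ddit4, an mTOR inhibitor, rose by 1.64 (SE 0.0829) and Cdkn1a by 0.58 (SE 0.0929, adjusted p = 0.000318), with 0.15 from 1 of its 2 other probes. Fas, a death receptor not above background at 0 h, was at least 1.71-fold higher. Among MYC targets and ribosome biogenesis genes, 13 of 24 were lower and 0 higher (17 and 0 adjusted over the list alone, median -0.33, adjusted p = 4.14e-05), with Rrp9 at -0.54 (SE 0.0987) and Nop2 at -0.53 (SE 0.0971). Myc itself was not above background at 24 h and at least 1.34-fold lower. Cholesterol synthesis genes had 10 of 18 lower, also adjusted over the list alone (median -0.29, adjusted p = 0.000777, adjusted p = 0.205 with an estimated correlation), with Fdps at -0.76 (SE 0.107) and Lss at -0.56 (SE 0.091). E2F targets had 6 of 32 lower (5 adjusted over the list alone, median -0.18, adjusted p = 0.0274, adjusted p = 0.264 with an estimated correlation), with E2f2 at -0.69 (SE 0.118, other probe -0.40). Without 0h replicate 2 their adjusted p was 0.109, and without 24h replicate 2 it was 0.0526.

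The genes called at 48 h of E1A against the control were compared with the earlier times, which share no array with them. Rec8, Cldn4, Krt18 and Krt8 were higher both at 24 h against 0 h and at 48 h against the control. Jam2, Klf4 and Pou5f1 were lower in both comparisons. Of the 2141 genes called at 48 h, 69.9% had a log2 fold change of the same sign at 24 h, called or not, against 57.8% of all genes. At 24 h, 467 were called higher both times where independent lists would share 195, and 355 lower both times against 153. In opposite directions, 82 were higher at 48 h and lower at 24 h and 147 the reverse. The share of the same sign was 62.2% at 3 h, 63.4% at 6 h, 67.3% at 9 h and 68.3% at 12 h.

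Some effects at 24 h and 48 h differed by limma's test of the difference itself. Acta1 was higher with E1A at 48 h and had a log2 fold change of -0.61 at 24 h (difference 3.82, SE 0.189, adjusted p = 3.51e-08). Egr1 had a log2 fold change of 1.35 against the control at 48 h and of -0.80 against 0 h at 24 h (difference 2.15, SE 0.122). Tcstv1, a gene of the 2-cell-like list, was at -1.54 against the control at 48 h and at 0.74 against 0 h at 24 h (difference -2.28, SE 0.161). The control itself was below 0 h for Egr1 and above 0 h for Tcstv1, so these opposite signs depend on the reference. The effects of Pou5f1, Sox2, Nanog and Esrrb differed by -0.13, -0.00089, 0.061 and -0.045, which did not pass the test (adjusted p = 0.465, 0.998, 0.811 and 0.85). In all, 1890 genes differed, 808 with a more positive effect at 48 h and 1082 with a more negative one. The reference is the cherry control at 48 h and the 0 h cells at 24 h, so time and reference change together.

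At 48 h of E1A against 0 h, Adssl1, a muscle adenylosuccinate synthase, was 16.6-fold and Rec8 12.5-fold higher, and Enox1 16.7-fold and Etv4, an ETS factor downstream of FGF signalling, 14.6-fold lower. Adssl1 rose by 4.06 on the log2 scale (SE 0.101), while its other probes gave 3.64 and 0.43. Rec8 rose by 3.64 (SE 0.0913, adjusted p = 1.82e-12) and Etv4 fell by 3.86 (SE 0.0868, adjusted p = 1.18e-12). Cpt1b, which carries fatty acids into mitochondria, was 8.37-fold higher, with 1 of 2 arrays above background at 0 h, at 3.07 on the log2 scale against 1.93 from its other probe. C2, complement component C2, was at least 6.77-fold higher, and Inhbb, not above background at 48 h, at least 8.35-fold lower. Myo1f, a myosin, fell by 2.97 (SE 0.138). In limma, 2925 genes were higher and 2754 lower, 5679 in all, 953 of them by at least 2-fold. The endoderm list had 13 of 18 members higher and 0 lower, also adjusted over the list alone (median 0.80, camera adjusted p = 1.04e-05), with the basement membrane collagens Col4a2 and Col4a1 at 1.80 (SE 0.102) and 1.66 (SE 0.0975). The trophectoderm list had 13 of 20 higher and 1 lower (13 and 2 adjusted over the list alone, median 0.63, or 0.58 with members at their bound, adjusted p = 0.00293), with Krt18 at 2.19 (SE 0.0994). MYC targets had 21 of 24 lower, also adjusted over the list alone (median -0.63, or -0.56 with members at their bound, adjusted p = 1.63e-07), with Pes1, a ribosome assembly factor, at -1.96 (SE 0.0882).

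Among pluripotency genes at 48 h of E1A against 0 h, 16 were lower and 3 higher, also adjusted over the list alone (median -0.45, or -0.41 with members at their bound, adjusted p = 0.00563). Utf1, an embryonic stem cell chromatin factor, fell by 2.50 (SE 0.103) and Pou5f1 by 1.69 (SE 0.0828, adjusted p = 9.4e-10). Esrrb and Klf4 had log2 fold changes of 0.15 and -0.14 (adjusted p = 0.181 and 0.3). Nanog rose by 0.41 (SE 0.101, adjusted p = 0.00297), with an adjusted p of 0.0512 without 0h replicate 2 and 0.143 with scaling to the 75th percentile. Primed epiblast genes had 9 of 12 lower and 2 higher, also adjusted over the list alone (median -0.77, or -0.56 with members at their bound, adjusted p = 0.0101, adjusted p = 0.124 with an estimated correlation, 0.146 with the stricter detection filter). Nodal, a growth factor of the epiblast, fell by 1.47 (SE 0.102). The retinoic acid list had 9 of 10 higher and 1 lower, also adjusted over the list alone (median 0.75, adjusted p = 0.0101, adjusted p = 0.0755 with an estimated correlation, 0.0674 with the stricter detection filter). Its member Tgm2, transglutaminase, rose by 1.62 (SE 0.14). E2F targets had 21 of 32 lower and 1 higher (23 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.00278, adjusted p = 0.0785 with an estimated correlation), with Rpa2, a replication protein, at -0.82 (SE 0.0954).

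**Figure D5:**
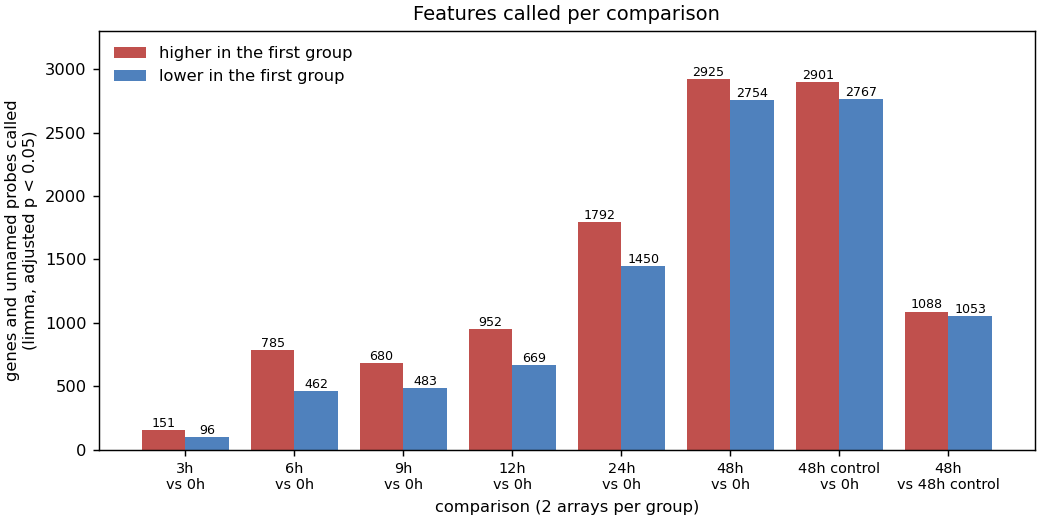
Number of genes called higher and lower in each of 8 comparisons (limma, adjusted p below 0.05, 9987 tested). The control differed from 0 h at 5668 genes, as 48 h of E1A did at 5679.

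The control changed almost as much over 48 h as the cells with E1A. Adssl1 was 17.9-fold higher in the control than at 0 h, Gsc, an organizer homeobox gene, 12.3-fold (1 of 2 arrays above background at 0 h), and Tgfbi and Rgcc, a cell cycle regulator, 9.42-fold and 9.34-fold. The other probes of Adssl1 gave 3.68 and 0.79 on the log2 scale, against 4.17, and the other probe of Tgfbi gave 2.15, against 3.24. Gsc changed by 3.62 (SE 0.135, adjusted p = 1.22e-10) and Enox1 by -3.62 (SE 0.119, adjusted p = 4.03e-11). Enox1 was 12.3-fold, Egr1 11.3-fold and Pes1 6.23-fold lower, and Ddx58, the RNA sensor RIG-I, not above background in the control, at least 5.9-fold lower. In limma, 2901 genes were higher and 2767 lower, 5668 in all, 903 of them by at least 2-fold. The labels leave open whether the constructs differ, so a change over time and a difference of construct are not separated here.

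In the control, 15 of 18 endoderm genes were higher than at 0 h and 0 lower, also adjusted over the list alone (median 0.74, or 0.72 with members at their bound, camera adjusted p = 1.09e-05, adjusted p = 0.0649 with an estimated correlation). Pdgfra, a receptor of the primitive endoderm, rose by 1.44 (SE 0.0935). All 11 members of the 2-cell-like list were higher, also adjusted over the list alone (adjusted p = 3.93e-05, adjusted p = 0.0531 with an estimated correlation), with Tcstv1 at 1.86 (SE 0.114) and Tcstv3 at 1.85 (SE 0.0852). MYC targets had 21 of 24 lower (22 adjusted over the list alone, median -0.55, or -0.54 with members at their bound, adjusted p = 3.04e-07), with Nop2 and Ncl, nucleolar proteins, at -1.33 (SE 0.0971) and -1.31 (SE 0.0893). E2F targets had 20 of 32 lower and 2 higher, also adjusted over the list alone (median -0.39, adjusted p = 0.000718, adjusted p = 0.0673 with an estimated correlation), with Ccne1 at -1.08 (SE 0.0893). Primed epiblast genes had 9 of 12 lower and 2 higher, also adjusted over the list alone (median -0.69, or -0.67 with members at their bound, adjusted p = 0.0137, adjusted p = 0.151 with an estimated correlation, 0.172 with the stricter detection filter), with Dnmt3b, a DNA methyltransferase, at -1.57 (SE 0.107). The stress response list had 13 of 26 higher and 2 lower, also adjusted over the list alone (median 0.25, adjusted p = 0.0137, adjusted p = 0.0673 with an estimated correlation), with Ddit3, the stress factor CHOP, at 3.17 (SE 0.138). With scaling to the 75th percentile its adjusted p was 0.0762. Pluripotency genes went both ways, 12 higher and 13 lower (median 0.089, adjusted p = 0.996). Klf4, Esrrb and Nanog rose by 0.98 (SE 0.109), 0.87 (SE 0.0909) and 0.79 (SE 0.101), while Pou5f1 fell by 0.79 (SE 0.0828).

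Core factors and cell cycle genes were also followed whatever their values. Against 0 h, Pou5f1 fell by 0.42 at 6 h (SE 0.0828, adjusted p = 0.00475, 0.0625 without 0h replicate 1), and its other probe gave -0.19. At 9 h it fell by 0.30 (adjusted p = 0.0297), with adjusted p of 0.222 without 0h replicate 1, 0.119 without 9h replicate 1 and 0.122 without 9h replicate 2. Nanog fell by 0.59 at 9 h (SE 0.101, adjusted p = 0.00159). Sox2 fell by 0.50 at 9 h (adjusted p = 0.038, 0.239 without 0h replicate 2, 0.242 without 9h replicate 1 and 0.0638 without 9h replicate 2) and by 0.70 at 12 h (adjusted p = 0.0046, 0.0608 without 0h replicate 2). The other Sox2 probe gave -0.12 at 6 h, -0.31 at 9 h, -0.19 at 12 h and -0.046 at 48 h of E1A. At 48 h of E1A Sox2 fell by 0.45 against 0 h (adjusted p = 0.0165, 0.163 without 0h replicate 2 and 0.127 without 48h replicate 1), while in the control its log2 fold change was 0.20 (adjusted p = 0.264, 0.0186 without 48h control replicate 1). At 3 h Esrrb was at -0.25 (adjusted p = 0.164) and Zfp42 at -0.024 (adjusted p = 0.935). Zfp42 fell by 0.40 at 6 h (adjusted p = 0.012, 0.0933 without 0h replicate 2 and 0.0886 without 6h replicate 1), by 0.95 at 48 h of E1A (SE 0.0937) and by 0.39 in the control (SE 0.0937).

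Cyclin E genes were called lower than at 0 h at 48 h in both arms and at no earlier time. Ccne1 fell by 0.64 with E1A (SE 0.0893, adjusted p = 2.72e-05), and Ccne2 fell by 0.95 with E1A (SE 0.178) and by 1.04 in the control (SE 0.178). From 3 h to 24 h Ccne1 had log2 fold changes of -0.0033, 0.049, 0.24, 0.15 and 0.0035 (adjusted p = 0.992, 0.766, 0.104, 0.277 and 0.981) and Ccne2 of -0.087, 0.23, 0.12, 0.041 and -0.35 (adjusted p = 0.859, 0.439, 0.732, 0.913 and 0.151). Rb1 rose by 0.66 at 24 h (SE 0.0975, adjusted p = 0.000161), by 0.75 at 48 h of E1A (SE 0.0975) and by 0.93 in the control (SE 0.0975), after values of 0.19, 0.22, 0.12 and 0.21 (adjusted p = 0.325, 0.167, 0.472 and 0.166). Without 12h replicate 2 the adjusted p of Rb1 at 12 h was 0.0286. Cdkn1a fell by 0.38 at 6 h (adjusted p = 0.0151, 0.104 without 0h replicate 2 and 0.106 without 6h replicate 2). It rose by 0.30 in the control (adjusted p = 0.0123, 0.0962 without 0h replicate 1 and 0.121 without 48h control replicate 2, other probes 0.53 and 0.18). At 3, 9 and 12 h and at 48 h of E1A it was at -0.23, -0.14, -0.022 and 0.075 (adjusted p = 0.221, 0.353, 0.909 and 0.516).

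Myc, a growth regulator, was at -0.14 at 3 h (adjusted p = 0.544) and was lower at 6 h, where 1 of 2 arrays was above background, so the size of the fall is not exact (adjusted p = 0.00507, 0.0571 without 0h replicate 2 and 0.0706 without 6h replicate 1). From 9 h it was not above background, at least 1.36-fold lower at 9 h (adjusted p = 0.00527, 0.0691 without 0h replicate 2), at least 1.34-fold at 12 h, at least 1.36-fold at 48 h of E1A and at least 1.38-fold in the control. Cdh1 rose by 0.31 at 24 h (adjusted p = 0.0135, 0.101 without 0h replicate 1 and 0.0966 without 24h replicate 1). At 48 h of E1A it rose by 0.23 (adjusted p = 0.0336, 0.19 without 0h replicate 1 and 0.254 without 48h replicate 2). At 3, 6, 9 and 12 h and in the control its log2 fold changes were 0.10, 0.15, 0.18, 0.23 and 0.12 (adjusted p = 0.571, 0.287, 0.2, 0.084 and 0.238).

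Both arms at 48 h shared many changes from 0 h, among them Adssl1, Vldlr, a lipoprotein receptor, and Ddit3, which rose in both, and Enox1 and Pes1, which fell in both. In all, 2258 genes were higher and 2126 lower in both, 77.2% of the calls at 48 h of E1A, and 95 went in opposite directions. Independent lists would share 849.6 and 763. The fold changes correlated across genes with r of 0.851, while unchanged groups set against the same 0 h arrays gave 0.5 in simulation. The covariance was 0.319 against a simulated 0.00727, and the same sign share 83.7% against 66.7%. Unchanged groups gave 0 simulated calls in both arms. The simulation holds no effects, so part of the excess of shared calls over independent lists may still come from the shared 0 h arrays. No split of these arrays was made, since it would leave each arm fewer than 2 of them. Over the E1A time course as a whole, limma's F test called 6260 genes, 62.7% of those tested.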

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

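The test of serum response factor targets and both tests of the control were chosen before their own values were seen, and the tests of the 2-cell-like genes and of fibroblast matrix genes after the result was seen. The results below differ between 24 h and 48 h of E1A by limma's test of the difference of effects, which called 1890 genes. The reference is 0 h for the first effect and the control at 48 h for the second.

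For some genes the effect at 48 h exceeded that at 24 h. The difference was 3.82 for Acta1 (3.21 at 48 h and -0.61 at 24 h, adjusted p = 3.51e-08), 2.03 for Acta2 (adjusted p = 9.69e-08), 2.21 for Lox (adjusted p = 8.16e-07) and 1.71 for Fgfbp1 (adjusted p = 1.73e-05). It was 2.15 for Egr1 (adjusted p = 9.69e-08), 0.43 for Ccne1 (adjusted p = 0.027) and 0.43 for Cldn4 (adjusted p = 0.0426). The value of 0.93 for Myc measures no difference, since Myc was not above background in either group at 48 h or at 24 h. The value of 0.89 for Rgma measures none either, since Rgma was not above background at 0 h and its rise at 24 h is a lower bound.

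In the other direction the difference was -2.83 for the dynein gene Dnaic1 (adjusted p = 9.4e-09), -2.34 for Ephx1 (adjusted p = 2.22e-07), -2.33 for Ccdc113 (adjusted p = 9.69e-08), -2.28 for Tcstv1 (adjusted p = 8.06e-07), -1.70 for Zscan4c (adjusted p = 9.1e-07) and -1.45 for Tmem92 (adjusted p = 0.000449), a size that is not exact since Tmem92 was not above background at 48 h of E1A. The value of -0.50 for Pramel7 measures no difference, since Pramel7 was not above background at 24 h or 48 h of E1A. It was -1.89 for Pramel20 (adjusted p = 1.27e-05), -1.87 for AF067063 (adjusted p = 0.000167), -1.74 for Vstm2l (adjusted p = 9.62e-05), -1.61 for Cbln1 (adjusted p = 0.000101) and -0.82 for Rec8 (adjusted p = 0.00056). For Rb1 it was -0.84 (adjusted p = 0.000798), for Cdkn1a -0.80 (adjusted p = 0.000746) and for Klf4 -0.54 (adjusted p = 0.0248). The value for Rb1 shows no fall with E1A. Its level against 0 h was 0.66 at 24 h, 0.75 at 48 h of E1A and 0.93 in the control. For Jam2 the difference was -0.60 (adjusted p = 0.00597). The 3 other Jam2 probes had larger falls at 24 h (-2.39, -2.11 and -1.76) than at 48 h (-1.52, -0.79 and -0.87). The direction for Jam2 thus depends on the probe.

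Of the lists, 9 differed by camera. The median difference was 0.25 for E2F targets (adjusted p = 0.00418), 0.22 for fibroblast markers (adjusted p = 0.011), 0.22 for mesenchymal transition (adjusted p = 0.0444), 0.33 for TGF-beta, SMAD and YAP targets (adjusted p = 0.00418), 0.30 for MYC targets (adjusted p = 0.00161) and 0.31 for immediate early genes (adjusted p = 0.00418). It was -0.41 for p53 targets (adjusted p = 0.00418), -1.03 for the 2-cell-like state (adjusted p = 9.26e-10) and -0.21 for oxidative phosphorylation (adjusted p = 0.0299). The positive differences of the MYC and E2F lists show no recovery with E1A, since the control was itself below 0 h. The MYC median against 0 h was -0.33 at 24 h, -0.63 at 48 h of E1A and -0.55 in the control. The E2F median was -0.18, -0.33 and -0.39. With an estimated correlation only the 2-cell-like list held its call (adjusted p = 0.0112). The mesenchymal list reached 0.0713 and oxidative phosphorylation 0.0705 with scaling to the 75th percentile, and the fibroblast list 0.367 with the stricter detection filter.

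The 2-cell-like genes were lower at 48 h of E1A than in the control. Whether signal shared between near-identical copies plays a part stays open. The single-copy members Tmem92 and Arg2 had a median of -1.35, but neither was above background with E1A, and their falls are only bounds of at least 3.28-fold and at least 1.43-fold. The direction did not rest on a single deviating array, since 11 of 11 members had both E1A arrays below both control arrays. This does not bound how much a single array adds to the size. A rise in the control that the E1A arm lacks fits, with a median change from 0 h of 0.97 in the control and -0.19 with E1A. With E1A, 4 members were called lower than at 0 h and 2 higher, so for some a fall with E1A also enters.

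Actin and fibroblast marker genes were higher at 48 h of E1A than in the control. Fibroblasts in the E1A samples were not seen in their abundant matrix genes, but a small share of them cannot be excluded. The 9 abundant fibroblast matrix genes on the array had a median of 0.038, and 7 of them were above background on no E1A array at 48 h. Ratios of genes below background say little, so this median cannot decide the question. Dcn, at 0.57, was above background on 1 E1A array and 0 control arrays, and Thy1, above background in both groups, was at -0.067. Activation of serum response factor fits the values but is not shown by them. Its 13 further target genes had a median of 0.23, above 99.8% of 10000 random lists of similar expression. Of these genes, 5 were called higher, among them Srf and Fhl2, and 2 lower, Mcl1 and Tuft1. The random lists drew genes independently, so genes regulated together can exceed them more easily. The activity of the factor was not measured. Against 0 h, Acta2 was at 0.971 with E1A and -1.18 in the control, so activation is not told apart from a fall in the control.

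The control arrays at 48 h were far from 0 h. An array batch holding only the arrays at 48 h is unlikely to be the whole cause, but its share is not bounded. The change from 12 h to 24 h had a slope of 0.19 on the change from 0 h to the control. The slope was 0.0505 for the change from 6 h to 12 h, and at most 0.00996 for 6 differences between replicates. A batch that sets the 0 h arrays apart was not tested. Whether the control contains RNA induced by E1A cannot be told, since the 952 genes called higher at 12 h had a median of 0.12 between E1A and control at 48 h and of 0.45 between control and 0 h.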

How the results depend on the processing

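The alternatives were chosen before the data were examined, except for the list tests added later, and none was chosen for its result. With 2 arrays per group, leaving one out leaves a lone array that is assumed to vary like the other groups, and most counts were lower with an array left out. The signal over background limits genes near the detection limit, whose folds are bounds. Among the named genes, 6586 values under the alternatives stayed on their side of the threshold, 11 crossed it upward and 196 downward. With an array left out these numbers were 2413, 2 and 409. Among values called in either setting, 0 changed sign. Sign changes among uncalled values were not counted, nor were genes that the stricter detection filter removed. The setting with all probes kept the chosen probe of each gene, so it does not compare probes. Of the list tests and the counts of called lists added later, 2820 stayed, 137 gained, 63 lost and 2 took the other direction. Neither of these 2 was called with the chosen settings. With an array left out 893 stayed, 14 gained and 9 lost.

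A minimum log2 fold change of 1 left 171 genes at 48 h of E1A against the control, 19 at 3 h, 38 at 6 h, 54 at 9 h, 70 at 12 h, 221 at 24 h, 953 at 48 h of E1A against 0 h, 903 in the control against 0 h and 1042 in the F test, by construction. At 3 h the count was 417 with no background correction, 383 with an offset of 50 and 372 with trend and robust fitting, and the cause was not tested. With only the compared groups in the fit it was 93 at 3 h, 769 at 6 h and 1063 at 12 h, where fewer samples estimate the spread. The rotation test fry, which asks whether a list moves one way at all, called 16 lists at 48 h of E1A against the control, 16 at 24 h and 24 in the control against 0 h. With an estimated correlation 3 lists were called at 24 h and 1 in the control. Under fry the germline list at 24 h (adjusted p = 0.0316) and the host partner list at 48 h of E1A against 0 h (adjusted p = 0.0434) were called higher. Camera gave both as lower but called neither (adjusted p = 0.619 and 0.986), so no call reversed. Camera compares a list with all other genes and fry does not, so their directions can differ. The cause was not tested further.

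Leaving out 1 array gave 1287 to 1656 genes at 48 h of E1A against the control, 80 to 157 at 3 h, 458 to 764 at 6 h, 546 to 724 at 9 h and 933 to 1238 at 12 h. The share with the same sign at 24 h was 68.6% to 73.5%. The other counts stayed within 1.5-fold.

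The replicate numbers share no stated source. Arrays of the same number deviated together in 23 of 28 pairs of groups, with correlations from -0.0875 to 0.303 (median 0.119). All negative pairs held the 0 h group, whose pairs ran from -0.0875 to 0.0488. Pairs without 0 h were all positive, from 0.042 to 0.303. With the replicate number as a block the counts were 2388 at 48 h of E1A against the control, 351, 1529, 1417, 1907 and 3585 from 3 h to 24 h, 5919 and 5865 at 48 h of E1A and in the control against 0 h, 6658 in the F test and 2193 for the difference of effects. Under the block immediate early genes at 6 h (adjusted p = 0.0736) and core histones at 12 h (adjusted p = 0.058) lost their calls. A block by slide was not run, since no slide is given.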

Other observations

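The motile cilium test was chosen before its own values were seen, and the gene families below were picked after the values were seen.

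Families of related genes did not move as one. Of the Id inhibitors of helix-loop-helix factors, Id4 rose by 1.35 (SE 0.101, adjusted p = 4.15e-07) and Id1 by 0.88 at 48 h of E1A against the control, while Id2 was at -0.10. Id3, not above background in the control, was at least 1.4-fold higher. Id1 rose by 1.00 at 3 h and fell by 0.57 at 24 h against 0 h. By 48 h Id1 was below its 0 h level in both arms, at -0.644 with E1A and -1.52 in the control. Of the D cyclins, which drive entry into S phase, Ccnd2 was higher than in the control by 1.71 and Ccnd1 by 0.89. Ccnd3 was lower by 0.43 (adjusted p = 0.00419). Ccnd1 was below its 0 h level in both arms, at -0.26 with E1A and -1.15 in the control. Ccnd2 was at 1.63 and -0.088 against 0 h, and Ccnd3 at -0.296 and 0.133. Keratins Krt7, Krt8 and Krt18 rose by 0.68, 1.19 and 1.26, and Krt19, not above background in the control, was at least 1.59-fold higher, while Krt42 fell by 1.64 (adjusted p = 8.14e-08). The claudins Cldn3, Cldn4 and Cldn6 rose by 1.52, 1.75 and 0.77, while Cldn9 was at -0.078 and Krt17 at 0.090.

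Several genes downstream of FGF and ERK signalling were lower at 48 h than at 0 h in both arms. With E1A and in the control, Dusp6 fell by 1.29 and 1.44, Spry4 by 1.88 and 2.20 (1 of 2 control arrays above background), Etv1 by 1.75 and 1.49, Etv5 by 1.40 and 0.75 and Etv4 by 3.86 and 2.10. Others of the family were not called lower in both arms, with values of 0.23 and -0.26 for Spred1, -0.16 and -0.25 for Il17rd and 0.37 and -0.039 for Dusp4, and -0.69 and 0.85 for Fgf4. The DNA methyltransferase Dnmt3b fell by 0.94 with E1A and 1.57 in the control, and its partner Dnmt3l by 1.30 and 1.68. Dnmt1 was at -0.060 and -0.24 (adjusted p = 0.68 and 0.0947), and Uhrf1 at -0.25 with E1A (adjusted p = 0.0547) and -0.41 in the control (adjusted p = 0.00367).

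Dnaic1 and Ccdc113, genes of motile cilia, were higher at 24 h of E1A than at 0 h, Dnaic1 by 1.78. A shared rise of motile cilium genes at 24 h was tested on 19 others and not found, with a median of 0.0019, above 44.3% of random lists. Of these, 3 were called higher (Ccdc114, Dnal1 and Cfap69) and 1 lower (Rfx2). A shared change of the 19 at 48 h of E1A against the control was not tested. In that comparison Dnaic1 and Ccdc113 were at -1.05 and -0.827. Several of the 19 were called lower there, among them Ccno at -0.973 and Capsl at -0.851. The largest positive value was 0.278 for Ccdc114, which was not called (limma, adjusted p = 0.0742).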
